A study of Mus musculus with 16 samples.

How the data were processed

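RNA from 16 preparations of mouse hepatic stellate cells, the retinoid-storing cells of the liver that become matrix-producing myofibroblasts after injury, was measured on 1 oligonucleotide array each. All preparations came from male Balb/c mice and were depleted of cells carrying F4/80, a macrophage surface protein, per the labels' protocols. The samples fell into 5 groups, namely quiescent (5 arrays), culture (3), coculture (2), bile duct ligation (3) and CCl4 (3). The series' design text gives coculture 3 samples, of which 1 was not analysed here.

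The values are log2 expression values per probe set as the authors deposited them, between 0.04 and 13.88, and GCRMA is named in the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, normalises the arrays to one another by quantiles and summarises the probes of each probe set. Its version and settings are not given in the sources used here. Because of this background step, unexpressed probe sets pile up near log2 2 (median of all probe sets on an array, 2.00 to 2.06), so a fold that starts from such a level depends on the background estimate. No detection calls were used here. The number of arrays limits the precision.

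The table held 45101 probe sets with 0 missing values, and 0 value columns were left without a sample. The platform annotation listed 35890 of them, 34958 with 1 gene symbol and 932 with several, and 9160 others that were not controls had no name there. For 34754 of the 34958 the Entrez identifier was found in the reference gene table, and 0 symbols changed. The 64 control probe sets and the probe sets with several symbols or none were left out of all tests. Each of the 18193 genes was represented by its probe set with the highest mean over the 16 arrays, a choice blind to group. The 7823 genes with a log2 value of at least 5 on at least 2 arrays were tested.

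One linear model with 5 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean expression), so that the small groups shared 1 estimate of the spread. The 7 comparisons were contrasts of group means, and a gene was called when its Benjamini-Hochberg adjusted p over the 7823 genes was under 0.05. Changes are log2 differences with standard errors from this fit, group values are means with standard deviations (SD), and all tests were two-sided. A log2 difference of 1 is a 2-fold difference.

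Gene groups were 19 lists of genes of stellate cell activation, matrix, signalling, inflammation, proliferation and metabolism, and 10 lists of markers of other liver and blood cells. Each list with at least 3 tested members (23 of 29) was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists within a comparison. The same test with a correlation estimated from the residuals of each list, and limma's fry, which tests whether a list's genes move on balance one way without reference to other genes, were run beside it. Of the lists called with the preset correlation, those also called with the estimated correlation numbered 0 of 3 in culture against quiescent, 0 of 11 in coculture against quiescent, 0 of 5 in coculture against culture, 5 of 17 after bile duct ligation, 3 of 14 after CCl4, 0 of 4 between the injuries and 0 of 10 in culture against the in vivo mean. With so few arrays the estimated correlations are imprecise. Fry called 1, 11, 5, 14, 12, 0 and 10 of the same lists. Where the text says that a list passed, did not pass or was called, it means camera at the preset correlation unless fry is named.

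The groups, comparisons, lists, filters, tests and all alternatives but 1 were chosen before the data were examined. So was the rule for the genes named in the text. Per comparison it took the 8 largest increases and the 8 largest decreases among called genes whose arrays did not overlap between the sides, skipping unnamed clones. In a direction with fewer than 5 such genes it took the 5 with the smallest p, stated as not called where they were not. It added up to 4 members with the smallest adjusted p of each list that passed, of which the text names a part, and a fixed set of activation and quiescence genes. Members of the marker lists named with their levels, members of other lists named beside their counts and Col4a5, Htra1, Mpzl2, Cygb, Plin2 and Tcf21 were chosen after their values were seen. Genes of the fixed set that stayed below the filter were not tested.

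Comparisons against quiescent cells share the same 5 control arrays. Overlaps of calls were therefore set beside the number independent lists would give, beside 100 simulations of unchanged groups against the shared arrays, and beside the values with the 5 quiescent arrays divided into 2 and 3 in all 20 ways. Coculture minus culture shares no array with the in vivo comparisons, and its correlations with them were set against the 10 ways to divide the 5 culture and coculture arrays.

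The fit was tested on simulated arrays with the real gene means and spreads, in which 200 of 7823 genes changed, over 5 draws per comparison. It recovered 70.0% of 2-fold and 96.6% of 4-fold changes in culture against quiescent, and 50.8% and 92.2% in coculture against culture. Between bile duct ligation and CCl4 it recovered 61.8% and 94.0%. False calls made up 3.81%, 6.41% and 4.18% of the calls in these 3 comparisons.

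Alternatives were no filter, a filter at log2 7, quantile normalisation of the deposited values, centring of each array, the mean of all probe sets of a gene, eBayes without a trend, array weights, fits on only the groups compared, the replicate number as a block, a test against a minimum change of 1.5-fold (treat), and each array left out in turn. An alternative that left out quiescent replicate 4, culture replicate 3 and CCl4 replicate 3 together was added after seeing the data. Over all genes tested, the median log2 difference in the 7 comparisons lay between -0.05 and 0.01.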

Results

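Transcript levels were measured in stellate cells in 5 states. Quiescent cells came from untreated mice and were plated for 24 h. Cultured cells were kept for 5 days in medium with 10% serum on plastic, and cocultured cells were kept in the same way with Kupffer cells, the resident macrophages of the liver, behind a transwell membrane that prevents contact. In vivo activated cells came from mice with the bile duct ligated for 15 days or from mice given 4 injections of carbon tetrachloride (CCl4, 0.5 µl per g body weight), models of biliary and toxic fibrosis, and were then plated for 24 h. Between 6803 and 7037 of 18193 genes reached log2 5 on an array. Pearson correlations across the tested genes lay between 0.929 and 0.983 for pairs within a group and between 0.773 and 0.969 for pairs from different groups. No pair of arrays shared more than 409 identical values out of 45101. The labels do not say which preparations came from separate animals, so p-values measure only the spread between these samples, which may be technical.

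Markers of the stellate lineage were high in every group. Des, which encodes desmin, lay between 7.83 and 8.86 in the 5 group means and was not called in any of the 7 comparisons, and Pdgfrb, the PDGF receptor beta gene, lay between 10.22 and 11.33. Acta2, the smooth muscle actin gene that marks myofibroblasts, was already at 11.56 ± 0.36 (SD, n = 5) in the quiescent cells. Of 24 macrophage and Kupffer cell markers only Cd68, a lysosomal gene, averaged log2 5 or more there (7.02), while Adgre1, which encodes F4/80, stood at 1.88 ± 0.16 and C1qb at 2.25 ± 0.18. Pparg and Ccl5, fixed for report, stayed below the filter, with quiescent means of 1.42 and 2.00.

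**Figure D1:**
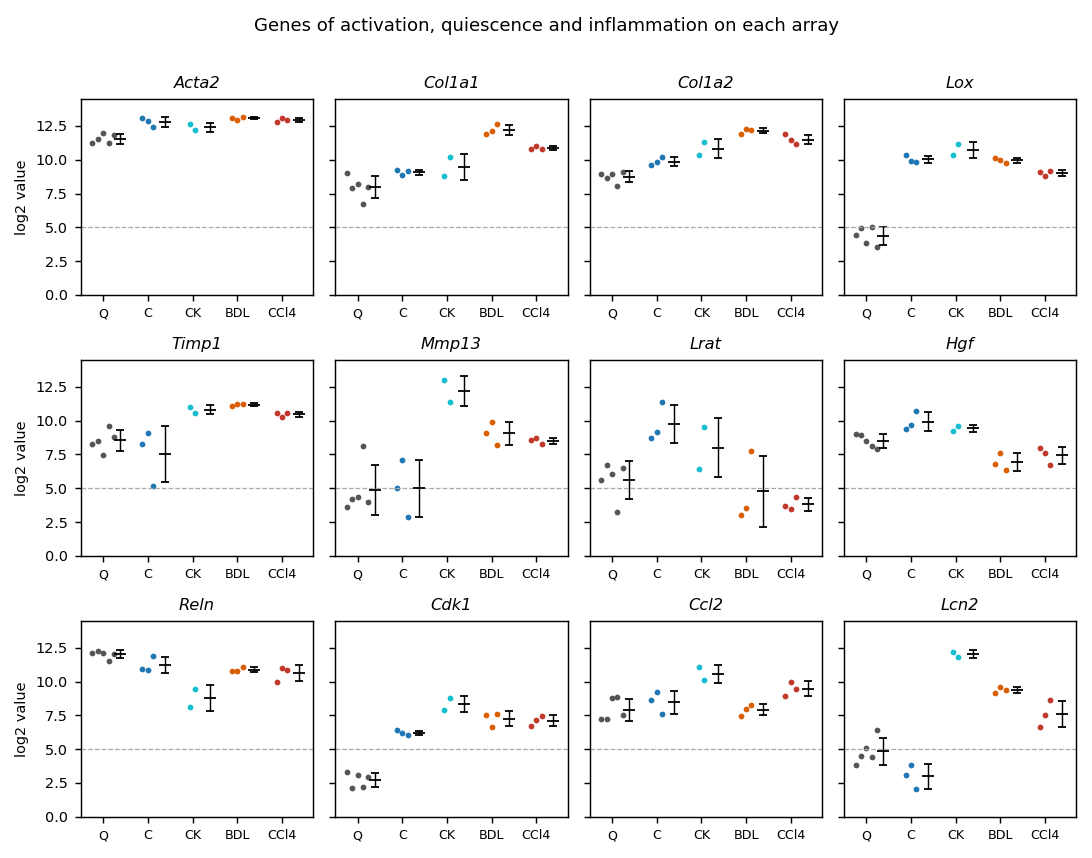
Log2 expression values of 12 genes in quiescent (Q), culture (C), coculture with Kupffer cells (CK), bile duct ligation (BDL) and CCl4 groups. Points are single arrays, bars the group mean with SD, and the dashed line is the filter at log2 5. Col1a1 stood at 12.22 after bile duct ligation and 9.09 in culture, while Lrat stood at 4.78 and 9.75.

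The first comparison asked how activation on plastic in serum changes quiescent cells. Ogn, a small matrix proteoglycan, rose by 7.61 ± 0.52 (log2 difference ± SE, adjusted p = 1.01e-07, limma), and the insulin-like growth factor carrier Igfbp3 rose by 5.89 ± 0.31 (adjusted p = 8.03e-09) to 12.88 ± 0.12 (n = 3). Lox, which cross-links collagen, went from 4.37 ± 0.67 to 10.03 ± 0.25, an increase of 5.66, and the basement membrane collagen gene Col4a5 rose by 6.40. Serpina1b (7.61), Shisa2 (6.76), Vegfd (5.64) and Clic5 (5.58) were the other large increases. The Serpina1b probe set is of a class that can also bind related sequences. The activation genes Acta2, Col1a1 and Col1a2 rose less, by 1.25 ± 0.19, 1.13 ± 0.38 and 1.12 ± 0.25. Col3a1 (1.13 ± 0.49, adjusted p = 0.0744), Timp1 (-1.03 ± 0.63), Mmp2 (0.28 ± 0.30), Mmp13 (0.12 ± 0.95, or 0.95 without quiescent replicate 4), Ccl2 (0.54 ± 0.44), Pdgfrb (0.10 ± 0.17) and Des (-0.12 ± 0.28) were not called. Without culture replicate 2 Timp1 was called (-1.81), and Col3a1 without quiescent replicate 2 (1.38) or either coculture array (1.13).

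The largest decreases in culture were those of the glutathione transferase Gsta2 (-6.07 ± 0.33, adjusted p = 9.84e-09), the matrix protein gene Tnxb (-5.20) and the protease inhibitor Serpinb2 (-4.95). Ntm (-4.57), the signalling genes Fosl1, Dusp5 and Egr3 (-4.46, -4.28 and -3.95) and the cytokine Il33 (-4.22) followed, with Egr3 not called without culture replicate 2 (-3.62). Of 21 tested genes of the oxidative stress response, 12 were lower and 3 higher (12 and 3 adjusted over the list alone). Srxn1 and Gclc, which serve peroxide repair and glutathione synthesis, fell by 3.33 ± 0.25 and fell by 2.09 ± 0.19. Gstp1 and Txn1 fell by 1.55 ± 0.08 and fell by 0.82 ± 0.07. The camera test of this list gave adjusted p = 0.0127, and adjusted p = 0.759 with an estimated correlation.

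Of 20 tested cell cycle genes, 12 were higher in culture and 3 lower (13 and 4 adjusted over the list alone). Cdk1, Ube2c and Birc5, which act in mitosis, rose by 3.48, 3.07 and 2.87, while Mcm2, part of the replicative helicase, fell by 1.44. Of 23 interferon response genes, 7 were higher and 16 not called (7 higher adjusted over the list alone), among them Ifit2 (2.39 ± 0.45) and Gbp2 (1.69 ± 0.31). The camera test gave adjusted p = 0.038 for cell cycle and 0.0255 for interferon response. These became adjusted p = 0.87 with an estimated correlation in both lists, and fry called neither (0.0695 and 0.173). The extracellular matrix list did not pass in camera, with 11 of 27 higher and 5 lower (11 and 5 adjusted over the list alone, adjusted p = 0.0978, but 0.0293 with fry), nor did the contractile list, with 7 of 24 higher and 5 lower (8 and 5 adjusted over the list alone, adjusted p = 0.417).

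Genes of quiescence and retinoid storage went both ways in culture, with 7 of 19 higher and 5 lower (7 and 6 adjusted over the list alone, adjusted p = 0.381). Lrat, which makes the retinyl esters stored in stellate cells, rose by 4.14 ± 1.04 (adjusted p = 0.00515) and the growth factor gene Hgf by 1.44 ± 0.37. Reln stood at 11.24 ± 0.60 against 12.03 ± 0.29 and was not called, but it was without quiescent replicate 4 (-0.91), culture replicate 3 (-1.13), either coculture array or CCl4 replicate 1 (-0.79). In all, limma called 3291 genes, 1450 higher and 1841 lower, of which 1323 differed at least 2-fold. The interferon call was lost without quiescent replicate 2 (adjusted p = 0.068), culture replicate 1 (0.173) or culture replicate 2 (0.244), and the cell cycle call without quiescent replicate 2 (0.0893) or 4 (0.0571) or culture replicate 1 (0.0863) or 3 (0.0575). The call of Col1a1 was lost without culture replicate 1 (1.06) or 3 (1.09), and with the mean of all probe sets of a gene those of Acta2 (0.41), Col1a1 (0.81) and Hgf (0.71) were lost. Without quiescent replicate 4, culture replicate 3 and CCl4 replicate 3 together, the calls of Lrat (2.74), Hgf (0.95) and Col1a1 (0.78) were lost. The cell cycle call was also lost with the filter at log2 7 (adjusted p = 0.945), the mean of probe sets (0.134), array weights (0.11) or centring (0.0521), and the interferon call with the filter at log2 7 (0.0818).

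Cocultured cells were next set against quiescent cells. The calcium-binding alarmin S100a8 rose most, by 8.26 ± 0.49 (adjusted p = 3.22e-08) to 9.88 ± 1.67 (n = 2), the stromelysin Mmp10 by 8.15 ± 0.94 and the collagenase Mmp13 by 7.34 ± 1.09 (8.17 without quiescent replicate 4). Matrix proteases and inhibitors as a list did not pass (7 of 18 higher and 4 lower, 7 and 4 adjusted over the list alone, adjusted p = 0.145), except with fry (0.00108), with no filter (0.0316) or without quiescent replicate 4, culture replicate 3 and CCl4 replicate 3 together (0.0417). Crct1, Saa3, Lcn2, Cd200 and Slco4a1 rose by 7.50, 7.35, 7.20, 7.02 and 6.47. Lox rose by 6.36 ± 0.35, Col1a2 by 2.07 ± 0.29, Col1a1 by 1.52 ± 0.44, Timp1 by 2.28 ± 0.72, Ccl2 by 2.66 ± 0.51 and Acta2 by 0.85 ± 0.21. Lrat (2.37 ± 1.19), Hgf (0.93 ± 0.42), Col3a1 (0.95 ± 0.56) and Des (-0.70 ± 0.32) were not called. Decreases were led by the glutathione transferases Gsta2 (-6.46 ± 0.38) and Gsta4 (-5.76 ± 0.37), followed by Robo2, Abi3bp, Col6a3, Gdf10, Ntm and Tnxb (-5.50 to -4.66). Reln fell by 3.25 ± 0.36, Mmp2 fell by 1.26 ± 0.35 and Pdgfrb fell by 0.66 ± 0.20. The calls of Acta2 (0.62), Mmp2 (-0.72), Timp1 (2.04) and Pdgfrb (-0.59) were lost without coculture replicate 2, and those of Col1a1 (0.83), Timp1 (2.51) and Pdgfrb (-0.73) without coculture replicate 3. Col3a1 was called without coculture replicate 2 (1.88) and Des without quiescent replicate 4 (-0.84), and with the mean of all probe sets Acta2 was not called (0.18).

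Lists of cell cycle and glycolysis genes were called in coculture against quiescent cells by camera with the preset correlation and by fry, but not with an estimated correlation. Of 20 cell cycle genes 19 were higher (19 adjusted over the list alone, adjusted p = 4.28e-14, and adjusted p = 0.22 with an estimated correlation), with Bub1, Cdk1, Birc5 and Rrm2 up by 5.04 to 5.62. Of 18 glycolysis and hypoxia genes 13 were higher and 1 lower (13 and 1 adjusted over the list alone, adjusted p = 8.69e-06, and adjusted p = 0.22 with an estimated correlation). They included the lactate exporter Slc16a3 (3.94), the hypoxia gene Bnip3 (3.81) and the glycolytic enzymes Tpi1 and Pgam1 (1.47 and 0.99). Among 15 collagen processing genes 7 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0159, and adjusted p = 0.322 with an estimated correlation), with P4ha2, which hydroxylates collagen, up by 1.83 ± 0.23. Among 21 endoplasmic reticulum stress genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.0159, and adjusted p = 0.425 with an estimated correlation), with Asns up by 1.28 ± 0.31 and the chaperone gene Hyou1 at -0.55 ± 0.16 (not called without coculture replicate 3, -0.33).

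Inflammatory lists also passed in this comparison. Of 23 interferon response genes 11 were higher and 12 not called (13 higher adjusted over the list alone, adjusted p = 0.000195, and adjusted p = 0.425 with an estimated correlation), with Irgm1 up by 2.62 ± 0.47 and Gbp2 by 2.18 ± 0.36. Of 18 NF-kB targets 7 were higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.0073, and adjusted p = 0.326 with an estimated correlation), with Cd40 up by 2.20 and Tnip1 by 1.58. Of 16 chemokine and cytokine genes 7 were higher (7 adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.425 with an estimated correlation), with Il6 up by 5.65 ± 1.20 and Cxcl14 by 4.82 ± 1.00. Of 5 complement and acute phase genes 4 were higher (4 adjusted over the list alone, adjusted p = 0.00241, and adjusted p = 0.322 with an estimated correlation), with Cfb up by 3.87 and C2 by 3.46. Oxidative stress genes were lower in 13 of 21 and higher in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.00066, and adjusted p = 0.22 with an estimated correlation). Immediate early and stress genes were lower in 8 of 21 and higher in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00742, and adjusted p = 0.462 with an estimated correlation), with the heat shock gene Hspa1b at -3.36 ± 0.70 and Klf2 at -2.42 ± 0.21.

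In coculture against quiescent limma called 3031 genes, 1396 higher and 1635 lower. Each coculture array weighed heavily, with 2014 genes called without replicate 2 and 1862 without replicate 3, where the lone array is assumed to vary like the other groups. The chemokine call was lost without quiescent replicate 2 (adjusted p = 0.0517), 3 (0.0682) or 5 (0.0645), coculture replicate 2 (0.193) or bile duct ligation replicate 2 (0.052) or 3 (0.0509). The endoplasmic reticulum stress call was lost without coculture replicate 2 (0.454), and the collagen processing call without coculture replicate 3 (0.0637) or with the filter at log2 7 (0.192). The chemokine call was also lost with this filter (0.0659) or the mean of probe sets (0.0662).

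What Kupffer cells added to culture was tested by coculture minus culture. The iron-binding lipocalin gene Lcn2 showed the largest increase and went from 2.99 ± 0.91 (n = 3) to 12.03 ± 0.28 (n = 2), an increase of 9.04 ± 0.66 (adjusted p = 1.06e-06). Serpinb2 rose by 8.83 ± 0.89, S100a8 by 8.11 ± 0.54, Mmp13 by 7.22 ± 1.19 and the cholesterol hydroxylase Ch25h by 6.51 ± 0.95. Matrix proteases and inhibitors as a list did not pass (7 of 18 higher and 5 lower, 7 and 5 adjusted over the list alone, adjusted p = 0.525), except with fry (0.0321) or with no filter (0.0405). Crct1, Prl8a9 and Fam110c rose by 6.26, 5.85 and 5.69. Timp1 rose by 3.31 ± 0.79 and the monocyte chemoattractant Ccl2 by 2.12 ± 0.56. Igfbp3 fell by 7.16 ± 0.39 (adjusted p = 6.53e-08), and Tgfbi, Mest, Angpt1, Colec10, Mamdc2, Ccdc141 and Ramp1 had differences of -5.75 to -4.57. Mmp2 fell by 1.54 ± 0.38 and Pdgfrb fell by 0.76 ± 0.22. Acta2 (-0.40 ± 0.23), Col1a1 (0.39 ± 0.48), Col1a2 (0.95 ± 0.31, adjusted p = 0.0531), Col3a1 (-0.18 ± 0.61), Lox (0.70 ± 0.38), Lrat (-1.77 ± 1.30), Hgf (-0.50 ± 0.46) and Des (-0.58 ± 0.35) were not called.

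All 20 tested cell cycle genes were higher in coculture than in culture (20 adjusted over the list alone, adjusted p = 1.22e-16, and adjusted p = 0.222 with an estimated correlation), with Bub1 up by 4.03 and the helicase genes Mcm5 and Mcm3 by 2.63 and 1.45. Of 18 glycolysis and hypoxia genes 11 were higher (11 adjusted over the list alone, adjusted p = 3.07e-06, and adjusted p = 0.222 with an estimated correlation), with Pkm, Pgk1 and Tpi1 up by 1.53, 1.30 and 1.20. Of 16 chemokine and cytokine genes 8 were higher (8 adjusted over the list alone, adjusted p = 0.000213, and adjusted p = 0.362 with an estimated correlation), with Cxcl5 up by 5.12, Ccl7 by 4.01 and Cxcl16 by 2.43. Of 18 NF-kB targets 7 were higher (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.00083, and adjusted p = 0.362 with an estimated correlation), with Saa3 up by 5.56 and the superoxide dismutase Sod2 by 1.17. Of 19 quiescence genes 8 were lower and 11 not called (8 lower adjusted over the list alone, adjusted p = 0.000386, and adjusted p = 0.362 with an estimated correlation), with Fgfr2, Reln and Pth1r at -2.67, -2.47 and -1.61.

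In this comparison limma called 1205 genes, 655 higher and 550 lower, 737 of them at least 2-fold. The share of higher calls, 54.4%, was 49.2% with each array centred. The count was 446 without coculture replicate 2, which also ended the calls of Timp1 (3.08), Ccl2 (1.65), Colec10 (-2.75), Pdgfrb (-0.70) and Mmp2, and a fit on these 5 arrays alone called 601. The calls of Ccl2 (1.67) and Pdgfrb (-0.79) were also lost without culture replicate 3, and that of Pdgfrb without culture replicate 2 (-0.72) or coculture replicate 3 (-0.83). Col1a2 was called without coculture replicate 2 (1.44), culture replicate 3 (1.13) or quiescent replicate 4 (0.95).

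Bile duct ligation was compared with the quiescent state at the same time of plating. Col1a1 went from 7.96 ± 0.82 (n = 5) to 12.22 ± 0.37 (n = 3), an increase of 4.26 ± 0.38 (adjusted p = 2.55e-06), Col1a2 rose by 3.40 ± 0.25 and Lox by 5.59 ± 0.30. Of 27 extracellular matrix genes 15 were higher and 12 not called (18 higher and 1 lower adjusted over the list alone, adjusted p = 1.87e-10, and adjusted p = 0.0283 with an estimated correlation). Fbln2 and Col15a1 rose by 5.82 and 4.04 and Col3a1 by 1.84. Of 24 contractile genes 11 were higher (12 adjusted over the list alone, adjusted p = 1.91e-09, and adjusted p = 0.0802 with an estimated correlation), with the smooth muscle genes Actg2, Cnn1, Lmod1 and Acta2 up by 5.17, 4.97, 3.39 and 1.51. Of 18 matrix proteases and inhibitors 8 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.000103, and adjusted p = 0.017 with an estimated correlation), with Mmp10, Mmp12 and Mmp13 up by 5.67, 4.63 and 4.22 and Timp1 by 2.63 ± 0.63. Without quiescent replicate 4 the change of Mmp13 was 5.04. Of 15 collagen processing genes 6 were higher and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.00089, and adjusted p = 0.0802 with an estimated correlation), with Loxl1 up by 3.42. The call of Col3a1 was lost without bile duct ligation replicate 2 (1.80) or 3 (1.74).

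The largest single increases after ligation were those of the surface glycoprotein Cd200 (6.14 ± 0.26, adjusted p = 1.55e-09), the chemokine Cxcl14 (5.93 ± 0.87), Fbln2 (5.82 ± 0.41) and Lyz1, a macrophage marker (5.81 ± 0.44). Lmcd1 rose by 5.42. Of 20 cell cycle genes 19 were higher (20 adjusted over the list alone, adjusted p = 2.59e-21, and adjusted p = 0.0461 with an estimated correlation), with Cdk1, Top2a and Rrm2 up by 4.53, 4.26 and 4.07. Of 18 glycolysis and hypoxia genes 5 were higher (5 adjusted over the list alone, adjusted p = 0.00199, and adjusted p = 0.185 with an estimated correlation), with the hexokinase Hk2 up by 3.43 ± 0.51. Of 21 endoplasmic reticulum stress genes 4 were higher (4 adjusted over the list alone, adjusted p = 0.00608, and adjusted p = 0.367 with an estimated correlation), with Creld2 up by 1.10 and Manf by 0.85. Of 5 complement genes 2 were higher (2 adjusted over the list alone, adjusted p = 0.0171, and adjusted p = 0.354 with an estimated correlation), with Serping1 up by 1.17.

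Genes of the quiescent state were lower after ligation. Of 19 quiescence and retinoid genes 8 were lower and 11 not called (9 lower adjusted over the list alone, adjusted p = 7.82e-05, and adjusted p = 0.195 with an estimated correlation), with Vipr1, Ecm1, Fgfr2 and Pth1r at -2.62, -2.15, -1.92 and -1.24. Hgf fell by 1.57 ± 0.37 and Reln fell by 1.13 ± 0.31. Lrat was at 4.78 ± 2.61 and not called. Of 23 interferon response genes 6 were lower (7 adjusted over the list alone, adjusted p = 0.00052, and adjusted p = 0.447 with an estimated correlation), with the immunoproteasome genes Psmb8 and Psmb9 at -2.16 and -2.11. Of 21 immediate early and stress genes 4 were lower (4 adjusted over the list alone, adjusted p = 0.00052, and adjusted p = 0.367 with an estimated correlation), with Klf2 and Klf4 at -1.25 and -1.19. Of 15 cholesterol genes 2 were lower, Sc5d and Lss (2 adjusted over the list alone, adjusted p = 0.00608, and adjusted p = 0.419 with an estimated correlation). Decreases of single genes were led by Abi3bp, Mamdc2, Ntm and Lrrn3 (-4.62 to -3.94), Acap1 and Mapt (-3.80 and -3.73), the succinate receptor Sucnr1 (-3.72) and the growth factor Gdf2 (-3.56). Mmp2 (-0.35 ± 0.30), Pdgfrb (-0.36 ± 0.17), Ccl2 (-0.02 ± 0.44) and Des (0.32 ± 0.28) were not called. Without bile duct ligation replicate 1 or 2 the call of Reln was lost (-1.10 and -1.08), and without replicate 3 that of Hgf (-1.27). The call of Lss was lost without quiescent replicate 3 (-0.67), 4 (-0.74) or 5 (-0.84), bile duct ligation replicate 1 (-0.59) or 2 (-0.78), culture replicate 2 or CCl4 replicate 2 or 3 (-0.82).

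Markers of other cells moved with these groups. Alb, the albumin gene of hepatocytes, went from 2.75 ± 0.94 to 8.25 ± 0.84 after ligation and the epithelial keratins Krt18 and Krt8 rose by 5.22 and 4.81. All 3 tested hepatocyte markers were higher (3 adjusted over the list alone, adjusted p = 0.000455, and adjusted p = 0.0802 with an estimated correlation), as were 2 of 4 cholangiocyte markers (3 adjusted over the list alone, adjusted p = 0.00052, and adjusted p = 0.0802 with an estimated correlation). Of 22 hepatocyte markers on the array only Alb, Ttr and Hpx were tested, and they passed the filter only through the injured arrays. The same holds for Krt8, Krt18, Dpt and Lrrn4. All 7 averaged 2.75 or lower in each group without injury. Their higher level after injury was thus fixed by the filter, and these counts and list tests are no separate support. The call of the hepatocyte marker Ttr was lost without bile duct ligation replicate 1 (2.15) or with the mean of probe sets (1.38), and that of the mesothelial marker Lrrn4 without replicate 2 (2.38) or 3 (2.46). Among portal fibroblast and mesothelial markers 3 of 4 were higher (4 adjusted over the list alone, adjusted p = 2.1e-05, and adjusted p = 0.017 with an estimated correlation), with Dpt up by 4.47. Among macrophage markers Lyz1 and Lyz2 of 3 were higher (2 adjusted over the list alone, adjusted p = 0.00657, and adjusted p = 0.142 with an estimated correlation). Among endothelial markers 3 of 4 were lower (3 adjusted over the list alone, adjusted p = 0.00199, and adjusted p = 0.0405 with an estimated correlation), with Bmp2, Ehd3 and Eng at -2.21, -1.99 and -0.90, the last not called without bile duct ligation replicate 1 (-0.82) or 2 (-0.77) or quiescent replicate 5 (-0.83). Only 4 of 23 endothelial markers were tested, and with no filter, which tests all 23, the list turned to higher after ligation (adjusted p = 0.0166). In all, limma called 1319 genes after ligation, 628 higher and 691 lower. The share of higher calls, 47.6%, was 55.4% after quantile normalisation and 56.0% with each array centred, so which direction has more calls depends on the scaling. The count was 784 without bile duct ligation replicate 1, the complement call was lost without replicate 3 (adjusted p = 0.0611) or with array weights (0.0537), and the endoplasmic reticulum stress call with the mean of probe sets (0.0606). Fry did not call the lists of endoplasmic reticulum stress (0.0663), interferon response (0.102) and cholesterol genes (0.0761).

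After CCl4, Col1a1 rose by 2.90 ± 0.38 to 10.86 ± 0.13 (n = 3, adjusted p = 8.36e-05), Col1a2 by 2.75 ± 0.25, Lox by 4.65 ± 0.30, Acta2 by 1.38 ± 0.19, Mmp13 by 3.65 ± 0.95 (4.48 without quiescent replicate 4), Timp1 by 1.94 ± 0.63 and Ccl2 by 1.54 ± 0.44. Of 27 extracellular matrix genes 11 were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 5.03e-05, and adjusted p = 0.117 with an estimated correlation), with Fbln2 up by 5.26 and Fn1 by 2.20. Collagen processing and cross-linking did not pass in camera (3 of 15 higher and 3 lower, 4 and 3 adjusted over the list alone, adjusted p = 0.263, but 0.00868 with fry). Of 24 contractile genes 8 were higher (9 adjusted over the list alone, adjusted p = 8.37e-06, and adjusted p = 0.189 with an estimated correlation), with Actg2, Myh11 and Cnn1 up by 4.15, 3.91 and 3.71. Of 18 matrix proteases and inhibitors 8 were higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 0.00137, and adjusted p = 0.0248 with an estimated correlation), with Mmp10 and Mmp12 up by 5.83 and 3.67. Of 18 NF-kB targets 6 were higher (6 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.325 with an estimated correlation), with Saa3 up by 6.24, the cyclooxygenase Ptgs2 by 5.67 and Lcn2 by 2.77. Of 16 chemokine and cytokine genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.0409, and adjusted p = 0.456 with an estimated correlation), with Cxcl14, Il6 and Cxcl5 up by 4.60, 4.32 and 3.50. Without CCl4 replicate 1 the calls of Mmp13 (3.64) and Il6 (3.97) were lost. The call of Timp1 was lost without any CCl4 array (1.87, 2.05 and 1.89) or quiescent replicate 1 (1.87), 2 (1.93), 3 (1.67) or 5 (2.00), and that of Ccl2 without quiescent replicate 1 (1.37) or CCl4 replicate 2 (1.27) or 3 (1.53).

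Ch25h showed the largest increase after CCl4 (6.64 ± 0.76, adjusted p = 2.65e-05), with the protease inhibitor Slpi (6.45 ± 0.54), Baiap2l1 (6.26 ± 0.34), S100a4 (6.08 ± 0.33) and Atp1b1 (5.99 ± 0.37) close to it. Of 20 cell cycle genes 18 were higher (18 adjusted over the list alone, adjusted p = 3.15e-17, and adjusted p = 0.0697 with an estimated correlation), with Cdk1, Top2a and Birc5 up by 4.37, 4.27 and 4.00. Of 18 glycolysis and hypoxia genes 7 were higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.00277, and adjusted p = 0.189 with an estimated correlation), with Egln3 up by 3.96. Of 21 endoplasmic reticulum stress genes 5 were higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.0122, and adjusted p = 0.451 with an estimated correlation), with Creld2 up by 1.21. Of 19 quiescence genes 8 were lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 3.21e-05, and adjusted p = 0.189 with an estimated correlation), with Vipr1, Pth1r, Fgfr2 and Ecm1 at -2.66, -2.21, -1.89 and -1.79. Reln fell by 1.40 ± 0.31 and Pdgfrb fell by 1.02 ± 0.17, while Hgf (-1.06 ± 0.37, adjusted p = 0.0502), Lrat (-1.81 ± 1.04), Col3a1 (1.09 ± 0.49), Mmp2 (-0.17 ± 0.30) and Des (0.06 ± 0.28) were not called. Hgf was called without quiescent replicate 4 (-1.16) or 5 (-1.21), culture replicate 1 or 3 or bile duct ligation replicate 2 or 3 (-1.06). The potassium channel gene Kcnj8 (-4.03), Ntm (-3.85), Abi3bp (-3.83), Gdf10 (-3.65), Mapt (-3.60), Abca8a (-3.58), Acap1 (-3.42) and Gdf2 (-3.34) led the decreases.

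Other-cell transcripts were higher after CCl4 as well. Alb reached 9.33 ± 1.42 (an increase of 6.58 ± 0.61, adjusted p = 3.52e-06), and Krt18 and Krt8 rose by 6.49 and 5.88. All 3 tested hepatocyte markers were higher (3 adjusted over the list alone, adjusted p = 7.52e-05, and adjusted p = 0.0697 with an estimated correlation), with replicate 3 the highest array for Alb, Ttr, Hpx and Fgb. As after ligation, these 3 markers, Krt8, Krt18, Dpt and Lrrn4 passed the filter only through the injured arrays. The counts and list tests that rest on them are no separate support for the rise. Of 4 cholangiocyte markers 2 were higher (3 adjusted over the list alone, adjusted p = 0.000124, and adjusted p = 0.0697 with an estimated correlation), of 4 portal fibroblast and mesothelial markers 3 (4 adjusted over the list alone, adjusted p = 1.13e-05, and adjusted p = 0.0248 with an estimated correlation), and of 3 macrophage markers 2 (2 adjusted over the list alone, adjusted p = 0.00584, and adjusted p = 0.146 with an estimated correlation). All 4 tested endothelial markers were lower (4 adjusted over the list alone, adjusted p = 0.000369, and adjusted p = 0.0248 with an estimated correlation), with Ehd3 at -2.25 and Egfl7 at -1.76, but with no filter the list of 23 was not called (adjusted p = 0.795). The 5′ control probe set for 18S ribosomal RNA averaged 10.04 ± 1.47 in this group against 7.42 ± 1.37 in quiescent cells, while 3′ minus 5′ differences of the Actb and Gapdh control probe sets lay between -0.46 and 0.60 on all 16 arrays. In all, limma called 1719 genes, 744 higher and 975 lower, and the share of higher calls, 43.3%, was 52.8% with each array centred. The count was 878 without CCl4 replicate 1. The chemokine call was lost without quiescent replicate 1 (adjusted p = 0.0513), 2 (0.062), 3 (0.076) or 5 (0.0641), bile duct ligation replicate 3 (0.0533) or CCl4 replicate 2 (0.0766), after quantile normalisation (0.0526), with centring (0.0718) and with the filter at log2 7 (0.0617), which also ended the calls of endoplasmic reticulum stress (0.0559) and glycolysis (0.0528). Fry did not call chemokines (0.11) or endoplasmic reticulum stress (0.0684).

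**Figure D2:**
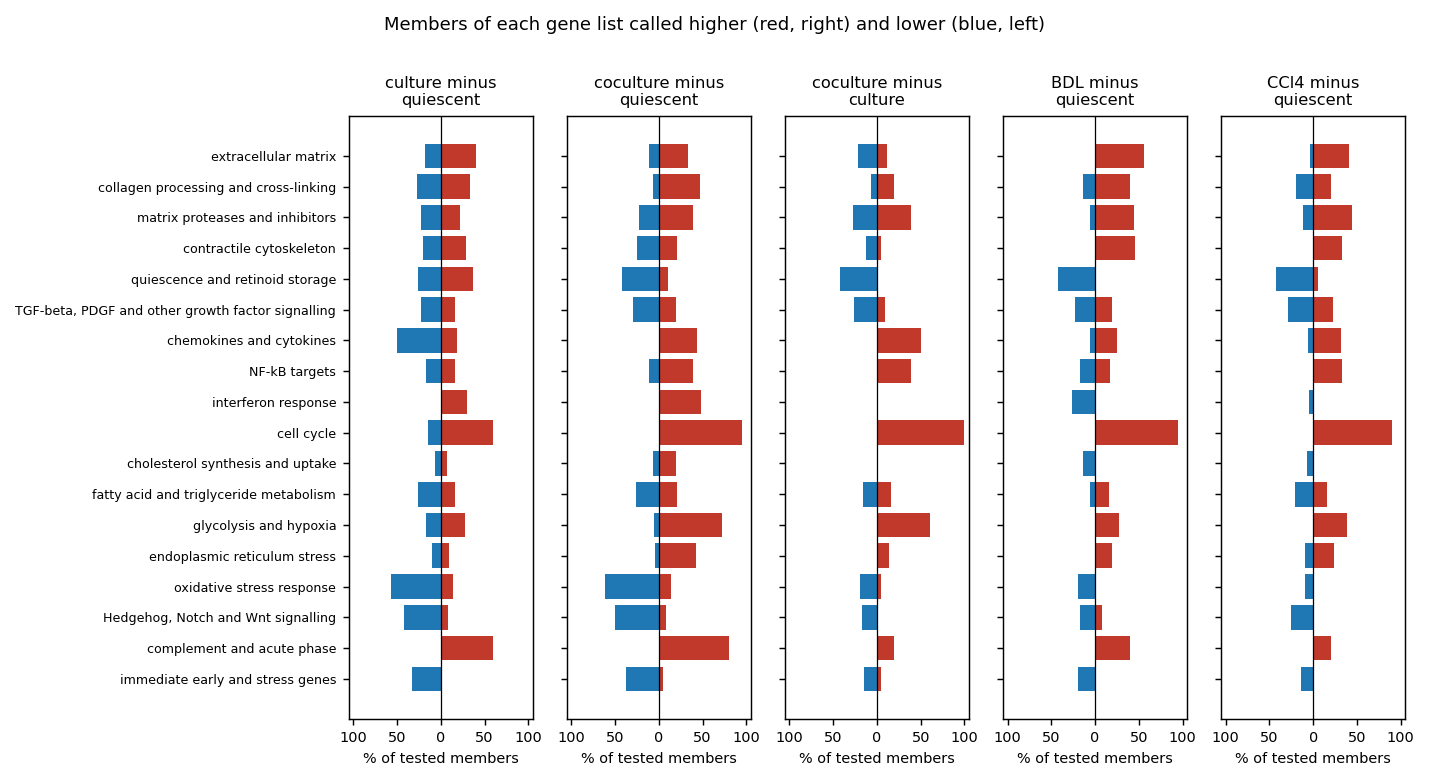
Percentage of the tested members of 18 gene lists called higher (red, to the right) or lower (blue, to the left) in 5 comparisons. Cell cycle bars reach 19 of 20 members after bile duct ligation and 18 of 20 after CCl4, against 12 of 20 in culture.

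**Figure D3:**
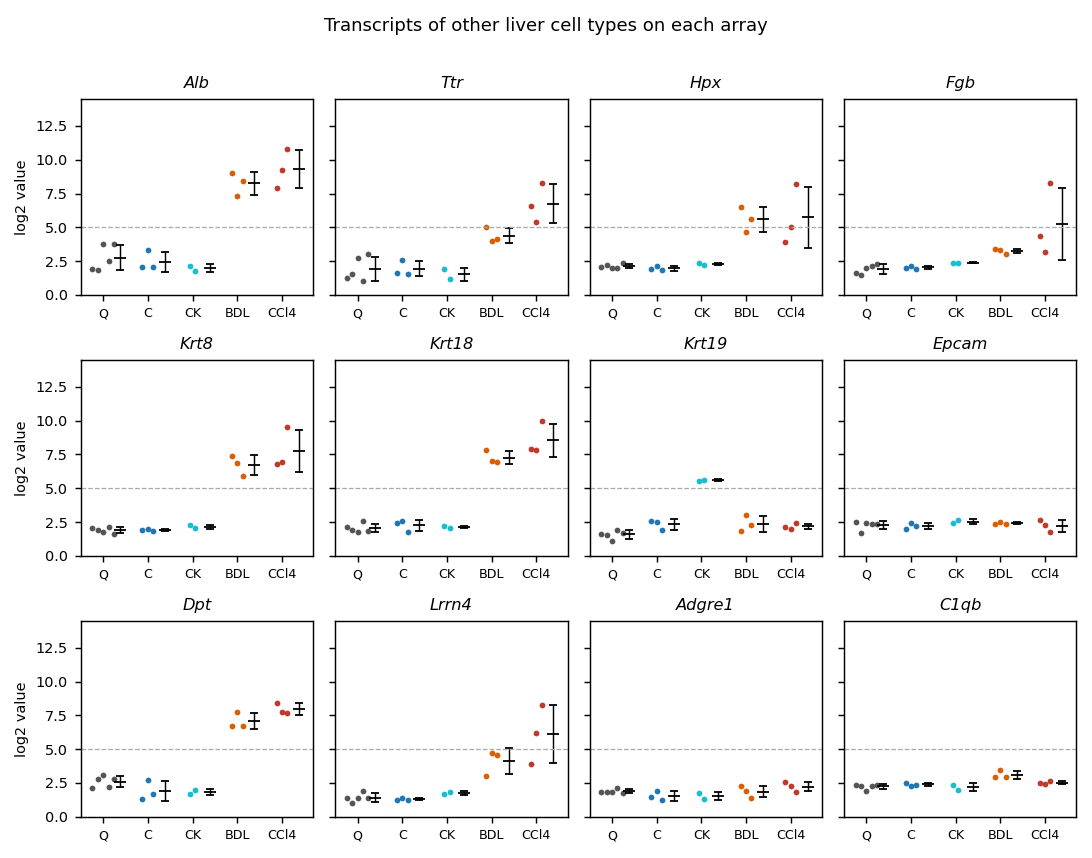
Log2 expression values of 12 transcripts typical of hepatocytes, epithelia, portal fibroblasts or mesothelium and macrophages in the groups quiescent (Q), culture (C), coculture with Kupffer cells (CK), bile duct ligation (BDL) and CCl4. Points are single arrays, bars the group mean with SD, and the dashed line is the filter at log2 5. Alb reached 8.25 and 9.33 in the injury groups, while Adgre1 stayed at 1.54 to 2.23 in every group mean.

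The injuries were compared directly. S100a4, which encodes a calcium-binding protein, and the fetal liver gene Afp were among 11 genes lower after ligation than after CCl4, with 2 genes higher (13 of 7823 called by limma, 1099 with an unadjusted p under 0.05). Afp stood at 3.03 ± 0.52 (n = 3) after ligation and 7.52 ± 1.28 (n = 3) after CCl4 (-4.49 ± 0.69, adjusted p = 0.00982), and S100a4 at 5.82 ± 0.22 and 9.09 ± 0.65 (-3.28 ± 0.36, adjusted p = 0.000426). Baiap2l1 differed by -3.69 ± 0.38, Bnc1 by -3.60 ± 0.51, Prkg2 by -2.99, Plscr2 by -2.97, the axon guidance gene Sema3a by -2.45 and Rnd1 by -2.30. Tmem119 (1.80 ± 0.34) and Adamtsl5 (1.39 ± 0.25) were higher after ligation, while Mn1 (1.76, adjusted p = 0.065), Mtch1 (0.94, adjusted p = 0.065) and Rnpepl1 (0.90, adjusted p = 0.0701) were not called. The collagen genes of the fixed set were not called, with Col1a1 at 1.36 ± 0.43 (adjusted p = 0.202), Col1a2 at 0.65 ± 0.28 and Col3a1 at 0.75 ± 0.55. The other genes of the fixed set also were not called, among them Ccl2 (-1.56 ± 0.50, adjusted p = 0.203), Pdgfrb (0.66 ± 0.19), Lox (0.94 ± 0.34), Lrat (0.97 ± 1.16), Acta2 (0.13 ± 0.21), Timp1 (0.70), Mmp13 (0.57), Reln (0.27), Des (0.26), Mmp2 (-0.18) and Hgf (-0.51). Of the called genes, Baiap2l1, Plscr2 and S100a4 stayed called in 27 of 27 alternatives and Bnc1 in 26 of 26. The calls of Afp (-4.20 and -3.75) and Sema3a (-2.16 and -2.50) were lost without bile duct ligation replicate 3 or CCl4 replicate 3, and that of Sema3a also without CCl4 replicate 1 (-2.26). Prkg2 kept its call in 14 of 25 alternatives, Rnd1 in 16 of 27, Adamtsl5 in 14 of 26 and Tmem119 in 12 of 26. Mtch1 was called without quiescent replicate 3 (0.94) and Rnpepl1 without quiescent replicate 4 (0.90).

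As lists, extracellular matrix (adjusted p = 0.000326, and adjusted p = 0.491 with an estimated correlation) and collagen processing (adjusted p = 0.00418, and adjusted p = 0.491 with an estimated correlation) leaned towards ligation. Interferon response (adjusted p = 5.7e-06, and adjusted p = 0.629 with an estimated correlation) and NF-kB targets (adjusted p = 0.0209, and adjusted p = 0.629 with an estimated correlation) leaned towards CCl4. Of their 27, 15, 23 and 18 tested members limma called 0 in any list, and 11, 6, 0 and 1 were higher and 1, 0, 4 and 4 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 matrix gene was higher and 1 NF-kB target lower, and the other counts were 0. The list medians were 0.37, 0.34, -1.13 and -0.31, and fry called 0 of these lists (adjusted p from 0.142 to 0.385). Hepatocyte (median -1.08, adjusted p = 0.119) and cholangiocyte markers (median -0.77, adjusted p = 0.119) leaned towards CCl4 without passing, and they were called without CCl4 replicate 1 (0.00632 and 0.0217) or 2 (0.0346 and 0.0299) and with no filter (2.77e-10 and 7.97e-05, all markers on the array tested). The mesothelial marker Lrrn4 stood at 4.11 after ligation and 6.13 after CCl4. The NF-kB call was lost without bile duct ligation replicate 1 (adjusted p = 0.191) or CCl4 replicate 3 (0.0895) or with the mean of probe sets (0.104). The number of called genes was 5 without bile duct ligation replicate 3 or CCl4 replicate 1, 4 without CCl4 replicate 3, 8 without culture replicate 2 and 20 without quiescent replicate 4.

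Activation on plastic was then tested against the mean of both in vivo models. Lrat was higher in culture by 5.46 ± 1.01 (adjusted p = 0.0004), as were Ogn (7.69), Shisa2 (7.24), the vessel growth factor Angpt1 (6.23), Igfbp3 (5.93), Mamdc2 (5.59), Ccdc141 (5.50) and Pdgfd (5.44). Serpinb2 differed by -8.00 ± 0.69 (adjusted p = 6.81e-07), and Alb (-6.33), Gsta2 (-6.18), Ch25h (-5.92), Sdc1 (-5.81), Fbln2 (-5.72), Krt18 (-5.66) and the caveolin gene Cav1 (-5.63) were also lower in culture. Col1a1 (-2.45 ± 0.37), Col1a2 (-1.95 ± 0.24), Timp1 (-3.32 ± 0.61) and Mmp13 (-3.81 ± 0.92) were lower in culture, and Hgf (2.75 ± 0.36) and Pdgfrb (0.79 ± 0.17) higher. Acta2 (-0.19 ± 0.18), Lox (0.55 ± 0.29), Col3a1 (-0.33 ± 0.47), Des (-0.31 ± 0.27), Reln (0.48 ± 0.30), Mmp2 (0.55 ± 0.29) and Ccl2 (-0.22 ± 0.43) were not called.

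Gene groups separated culture from the in vivo models. Of 20 cell cycle genes 17 were lower in culture (17 adjusted over the list alone, adjusted p = 2.13e-05, and adjusted p = 0.49 with an estimated correlation), with Mcm6 and Mcm5 at -2.43 and -2.23. Of 24 contractile genes 13 were lower (13 adjusted over the list alone, adjusted p = 0.0127, and adjusted p = 0.576 with an estimated correlation), with Cnn1 and Lmod1 at -3.11 and -3.02. Of 21 oxidative stress genes 11 were lower and 4 higher (11 and 4 adjusted over the list alone, adjusted p = 0.0279, and adjusted p = 0.36 with an estimated correlation), with Srxn1 at -2.69 and Sod3 at 4.04. Of 16 chemokine and cytokine genes 9 were lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.0305, and adjusted p = 0.576 with an estimated correlation), with Cxcl14 and Il33 at -4.84 and -4.38 and Cxcl10 at 4.40. Of 19 quiescence genes 14 were higher in culture (14 adjusted over the list alone, adjusted p = 0.000117, and adjusted p = 0.36 with an estimated correlation), with Bco1, Fgfr2 and Tcf21 at 3.67, 2.93 and 2.22. Of 23 interferon response genes 15 were higher (15 adjusted over the list alone, adjusted p = 0.000617, and adjusted p = 0.576 with an estimated correlation), with Psmb9 and Ifit2 at 2.65 and 2.54, and of 15 cholesterol genes 6 (6 adjusted over the list alone, adjusted p = 0.0305, and adjusted p = 0.576 with an estimated correlation).

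Hepatocyte markers were lower in culture than in vivo in 3 of 3 (3 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.36 with an estimated correlation) and portal fibroblast and mesothelial markers in 3 of 4 (3 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.333 with an estimated correlation). The 3 hepatocyte markers, Dpt and Lrrn4 passed the filter only through the injured arrays, so their lower level in culture was fixed by it. Endothelial markers were higher in 3 of 4 (4 adjusted over the list alone, adjusted p = 0.0305, and adjusted p = 0.333 with an estimated correlation), with Ehd3, Eng and Bmp2 at 4.02, 0.94 and 0.81, and with no filter the list of 23 leaned the other way (adjusted p = 0.725). The call of Bmp2 was lost without culture replicate 2 (0.71) or 3 (0.47), bile duct ligation replicate 3 (0.77) or CCl4 replicate 3 (0.63). In all, limma called 3984 genes, 1955 higher and 2029 lower in culture. Without culture replicate 3 the chemokine (adjusted p = 0.126) and cholesterol (0.0755) calls were lost, as they were with array weights (0.118 and 0.0577), and the mean of probe sets ended the cholesterol (0.0657) and oxidative stress (0.0625) calls.

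Each activation route was also compared by its calls against quiescent cells. Bile duct ligation and CCl4 shared 906 genes called in the same direction, 459 higher and 447 lower, and 1 gene called in opposite directions. Independent lists of these sizes would share 146. Simulated unchanged groups against the shared quiescent arrays gave 0. Groups without changes have hardly any calls to share, so this value cannot show how far shared controls raise the overlap of long lists. Culture shared 415 genes in the same direction with ligation and 576 with CCl4, against 279 and 367 for independent lists, and had 186 and 236 in opposite directions, against 276 and 356. Coculture shared 669 with ligation and 973 with CCl4, against 256 and 337, and had 69 and 50 in opposite directions. Culture and coculture shared 1843 (644 for independent lists). With the quiescent arrays divided so that no control was shared, the medians over 20 divisions were 504 for ligation and CCl4, 258.5 and 335 for culture with each injury, 438.5 and 609.5 for coculture with each injury and 1259 for culture with coculture. Leaving out CCl4 replicate 1 lowered the overlap of culture with CCl4 to 314 and of coculture with CCl4 to 531, and without coculture replicate 2 the latter was 636. Leaving out bile duct ligation replicate 1 gave 442 with coculture and 586 with CCl4, and without coculture replicate 3 the overlap of culture with coculture was 1141.

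Across genes, log2 differences of the injuries correlated with r = 0.85 (covariance 0.531, against 0.0264 from shared controls alone). For culture the values were r = 0.211 with ligation (covariance 0.151, against 0.0268) and r = 0.248 with CCl4 (0.187, against 0.0265), and for coculture r = 0.536 (0.438, against 0.0265) and r = 0.61 (0.526, against 0.0264). Simulated unchanged groups had mean r of 0.327 to 0.379, but their differences hold noise alone, so these r are no baseline for groups with real changes. The covariances lie above the simulated ones. With the quiescent arrays divided so that no control was shared, the median r of culture was 0.163 with ligation (0.00195 to 0.349 over 20 divisions). With CCl4 it was 0.205 (0.0361 to 0.373). The medians were 0.468 and 0.559 for coculture with ligation and CCl4, and 0.741 for the injuries. Genes are not independent replicates, and these correlations are across genes.

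Whether Kupffer cells moved cultured cells towards the in vivo profile was tested on coculture minus culture, which shares no array with the injury comparisons. Across 7823 genes it correlated with the change after ligation (r = 0.437, Spearman rho = 0.382) and after CCl4 (r = 0.489, rho = 0.493). The highest values among the other 9 divisions of the 5 arrays were r = 0.272 and r = 0.336, and with 10 divisions the share cannot go below 0.1. The lowest were r = -0.43 and r = -0.473, close in size to the real values, so the real division stands apart only in the positive direction. Genes called higher after ligation had a median coculture effect of 0.56 and genes called lower one of -0.35, and after CCl4 the medians were 0.54 and -0.42. The differences of 0.91 and 0.96 compare with at most 0.37 and 0.34 in the other divisions. Of the 1205 genes called in coculture minus culture, 391 had the same direction as after ligation and 55 the opposite, and 505 and 49 after CCl4, where independent lists would give 101 and 102, and 131 and 134. The root mean square log2 distance of single coculture arrays from ligation arrays averaged 1.01 (6 pairs) and from CCl4 arrays 0.944, against 1.15 and 1.14 (9 pairs each) for culture arrays. The ranges overlapped at their ends, at 0.981 to 1.04 against 1.03 to 1.27 for ligation and 0.863 to 1.01 against 0.997 to 1.29 for CCl4. The pairs reuse the same arrays and are not replicates.

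Remaining lists complete the account of other cells and pathways. None of 16 T and NK cell, 13 B and plasma cell or 5 erythroid markers on the array reached log2 5 on any of the 16 arrays. Of 12 neutrophil markers only S100a8, Mmp8 and Lcn2 reached it, with S100a9, Ngp and Mpo at 1.30, 1.40 and 1.40 in coculture. Of 11 dendritic cell markers Bst2 and Zbtb46 did, and Bst2 is also an interferon response gene. Among MHC class II and antigen presentation genes only Ctss and Ifi30 were tested. Growth factor signalling was called by camera in no comparison with the filter at log2 5 and all arrays, with 3 of 31 tested members higher and 8 lower in coculture minus culture (5 and 8 adjusted over the list alone, adjusted p = 0.0533, the lowest of the 7). Neither Hedgehog, Notch and Wnt signalling (1 of 12 higher and 6 lower in coculture against quiescent, 1 and 6 adjusted over the list alone, adjusted p = 0.0687) nor fatty acid and triglyceride metabolism (3 of 19 higher and 4 lower after CCl4, 3 and 4 adjusted over the list alone, adjusted p = 0.274, with the lowest adjusted p = 0.063 between the injuries) was called there by camera. Fry called growth factor signalling in culture against quiescent (0.0198), coculture minus culture (0.00578) and culture against the in vivo mean (0.00251). It called Hedgehog, Notch and Wnt signalling in coculture against quiescent (0.00354) and after CCl4 (0.0142), and fatty acid metabolism after CCl4 (0.0325). With the filter at log2 7, growth factor signalling was called in coculture minus culture (adjusted p = 0.00273) and in culture against the in vivo mean (0.0433). With no filter, Hedgehog, Notch and Wnt signalling was called in coculture minus culture (0.0337) and fatty acid metabolism between the injuries (0.0196). Without coculture replicate 3, growth factor signalling (adjusted p = 0.00994) and Hedgehog, Notch and Wnt signalling (0.0453) were called in coculture minus culture, and the latter in coculture minus quiescent (0.0231, and 0.0433 without quiescent replicate 4). Growth factor signalling was also called in coculture minus culture without culture replicate 2 (0.0336). Fatty acid genes were called between the injuries without bile duct ligation replicate 1 (0.0442) or 3 (0.02) or CCl4 replicate 3 (0.0433). In coculture against quiescent, Lyz1 and Lyz2 of 3 macrophage markers rose by 5.50 and 3.47 (2 adjusted over the list alone, adjusted p = 0.0209, adjusted p = 0.322 with an estimated correlation, and 0.39 with no filter), while Adgre1 and C1qb stood at 1.55 and 2.19.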

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

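The tests of explanations and of array divisions in this part, and their limits (the share of a list's markers, a median plus its SD, log2 8), were chosen after the results were seen. Quiescent replicate 4 stood apart from the other 4 quiescent arrays in 3 of 19 measures, where chance alone would set about 1 in 20 apart. Its median correlation with its group was 0.933 against 0.962 to 0.968 (gap over range 0.82), its Mmp13 value 8.16 against 3.61 to 4.38 (0.83) and its Reln value 11.52 against 12.07 to 12.26 (0.743).

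The injuries differed, by a test of the difference itself, in Afp (-4.49), Baiap2l1 (-3.69), Bnc1 (-3.60), S100a4 (-3.28), Prkg2 (-2.99), Plscr2 (-2.97), Sema3a (-2.45), Rnd1 (-2.30), Mpzl2 (-2.27), Htra1 (-2.17), Col4a5 (-1.91), Adamtsl5 (1.39) and Tmem119 (1.80). The 3 genes Mpzl2, Htra1 and Col4a5 fall outside the rule for named genes and kept their calls in 17 of 25, 20 of 26 and 21 of 27 alternatives. The median level of 22 hepatocyte markers was 2.23 after ligation and 3.36 after CCl4, while that of 24 macrophage markers was 2.89 and 2.29. Whether RNA of other cells contributes to the differences between the injuries was not tested. Culture and the in vivo mean differed in Col1a1 (-2.45), Col1a2 (-1.95), Timp1 (-3.32), Mmp13 (-3.81), Hgf (2.75), Lrat (5.46) and Pdgfrb (0.79). Genes called in opposite directions against the shared quiescent arrays numbered 186 for culture and ligation and 236 for culture and CCl4, and a difference between the sides follows from these calls and is no further test. Of the 186, 120 were higher in culture and 66 lower, and of the 236, 148 were higher and 88 lower.

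In the 5 comparisons with at least 3 arrays a side, the number of calls was set against the other ways to divide the arrays. The real division was the only 1 with as many calls among 56 for culture against quiescent (3291, highest other 522), 56 for ligation (1319, highest other 104), 56 for CCl4 (1719, highest other 271) and 84 for culture against the 6 in vivo arrays as 1 group (3884, highest other 21). Between the injuries it was 1 of 10 (13 calls, highest other 1), too few divisions to decide.

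The first pattern weighed is the rise of Alb, Krt8 and Krt18 after injury, for which RNA of other cells was weighed. Hepatocyte markers lay above every quiescent array on every injured array in 8 of 22 after ligation, which leaves hepatocyte RNA open there, and in 13 of 22 after CCl4, where it goes with the pattern (0.393 if no gene differed between the groups). The 22 include Alb itself, a gene of the pattern, which is no separate support. Many genes did differ, with 1152 of 7823 tested genes called without overlap in either direction after ligation and 1506 after CCl4. Array medians were also slightly higher after injury (2.05 to 2.06, against 2.00 to 2.03 in quiescent cells). Lists unrelated to other cells could thus also exceed such a value, and it is no measure of chance here. Portal fibroblast and mesothelial markers lay above every quiescent array on every injured array in 9 of 15 after ligation and 11 of 15 after CCl4 (0.268 if no gene differed), so RNA of such cells may contribute in both models. Cholangiocyte markers other than Krt8 and Krt18 did so in 1 of 12 after ligation and 5 of 12 after CCl4 (0.214 if no gene differed). Their median change after ligation was 0.105, against 4.81 for the smaller keratin change. All of them but Ezr averaged 2.75 or lower after ligation, near background, and how they respond to cholangiocyte RNA is not known. Cholangiocyte RNA is therefore left open in both models. Expression of these genes by stellate cells themselves was not tested, and transcript levels alone cannot separate it from RNA of other cells.

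The second pattern is the lower level of quiescence genes after injury, where the design gives injury in vivo as the biological difference. Dilution by RNA of other cells would lower all members alike only if those cells express none of them, which was not measured. The SD of the changes of the 13 members at log2 8 or more was 1.92 times their median standard error after ligation and 2.27 times after CCl4. The decreases were thus unequal, which dilution by RNA without these genes would not give. Members also expressed in the other cells would fall less, so the test cannot exclude dilution as the cause. The members ran from -2.15 (Ecm1) to -0.11 (Tcf21) after ligation and from -2.67 (Cygb) to -0.01 (Plin2) after CCl4, and the median change would need 62.7% and 60.9% of the RNA to come from other cells. With arrays centred or quantile normalised, the median change of all 19 tested members stayed at -1.18 or lower after ligation (SD 0.817) and at -1.26 or lower after CCl4 (SD 0.943). The median change over all genes was only -0.05 in both comparisons before this step, so an offset visible in array medians is far smaller than these decreases. GCRMA already normalises by quantiles, so the step could move the list little. It cannot decide on an array-wide difference that the first normalisation hid. GCRMA itself was not rerun here, and dilution could contribute to the decreases. Of the 147 other-cell markers below log2 5 in quiescent cells, 5 reached log2 8 after injury. Of these, Lcn2, Fbln2 and Lyz1 also averaged 12.0, 6.86 and 7.99 in coculture, without injury, so their levels are weak support for RNA of other cells. Alb and Krt18 stood at 1.96 and 2.12 in coculture.

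The third pattern is the resemblance of the coculture effect to the in vivo changes, where the design gives the presence of Kupffer cells as the biological difference and no signal from them was tested. RNA of Kupffer cells would raise their markers, but the median change of 24 macrophage markers in coculture minus culture was 0.0322 (SD 1.11) against 1.24 for genes called higher. The margin is narrow, with 5 of the 24 markers higher on both coculture arrays and Cd68 up by 4.08. The value of 1.24 comes from genes selected as higher in this same comparison, and only 3 of the 24 markers passed the filter. The test therefore cannot exclude RNA of Kupffer cells. A single aberrant array is ruled out, with the correlation at 0.403 or more for ligation and 0.439 or more for CCl4 whichever array was left out. With 2 coculture arrays, a difference between preparations that both share could not be tested.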

How the results depend on the processing

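The alternative that left out 3 arrays together was chosen after the results were seen, and the other alternatives before. Named genes kept their side of the threshold, without a reversed call, in 96.8% of 11350 values (281 weaker, 82 stronger, 0 reversed). Among those kept, 41 values that were not called changed sign. The list tests did so in 4398 of 4648 (121 weaker, 127 stronger, 2 reversed), and 111 of those kept changed direction without being called. Many named genes were chosen for large changes, and many alternatives left out an array outside the comparison, which favours high shares. Of all genes called after CCl4, 50.1% were kept without CCl4 replicate 1, against 97.9% without culture replicate 3. Ligation kept 58.2% without bile duct ligation replicate 1, and coculture minus culture 63.8% without culture replicate 3. With no filter the endothelial marker list (23 members tested rather than 4) turned its direction, at adjusted p = 0.0166 after ligation and 0.725 in culture against the in vivo mean. Calls between the injuries (13) numbered 43 with no filter, 4 with the filter at log2 7, 20 with the mean of all probe sets, 173 with array weights, 40 with only the groups compared, 5 with treat and 8 with quiescent replicate 4, culture replicate 3 and CCl4 replicate 3 left out. The fit of the array weights stopped before reaching its tolerance, with the largest weight at 5.79 for culture replicate 2. With array weights culture shared 644 genes with ligation and 885 with CCl4. With only the groups compared, coculture minus culture had 601 calls.

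With treat the calls were 761 (culture against quiescent), 745 (coculture against quiescent), 266 (coculture minus culture), 298 (ligation), 313 (CCl4) and 1165 (culture against the in vivo mean), since treat asks for more than 1.5-fold. The shared calls were then 82 and 83 (culture with ligation and CCl4), 160 and 173 (coculture with ligation and CCl4), 197 (both injuries) and 311 (culture with coculture), and the median differences 2.11 and 2.23. With the replicate block the correlation of the coculture effect with ligation was 0.478, the median differences 1.22 and 1.29, the overlap of culture with CCl4 379 and the lists called in coculture minus culture 9. Replicate numbers were not taken to pair the arrays, since 7 of 26 same-numbered pairs had r above 0.1 (median -0.01) and 5 of 16 arrays correlated best with their own number. The 2 pairs of culture with coculture had the highest values (0.31 and 0.54), too few to decide, and coculture minus culture had 1356 calls with the block.

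Lists called with the estimated correlation numbered 0 (culture, coculture, coculture minus culture), 5 (ligation), 3 (CCl4), 0 (between injuries) and 0 (culture against in vivo). With fry they were 5 (culture), 17 (coculture), 11 (coculture minus culture), 0 (between injuries) and 17 (culture against in vivo). The filter at log2 7 (5420 genes) left 1 list in culture and 8 after CCl4, no filter (18193 genes) gave 12 in coculture minus culture and 11 between the injuries, and quantile normalisation gave 8 in coculture minus culture. The cause of these shifts was not tested.

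Leaving out 1 array at a time moved the calls to 2580 to 3307 (culture), 1862 to 3130 (coculture), 446 to 1400 (coculture minus culture), 784 to 1433 (ligation), 878 to 1890 (CCl4), 4 to 20 (between injuries) and 3215 to 4160 (culture against in vivo). Shared calls ran from 314 to 601 (culture and CCl4), 442 to 705 (coculture and ligation), 531 to 1037 (coculture and CCl4), 586 to 1017 (both injuries) and 1141 to 1851 (culture and coculture). The correlations ran from 0.403 to 0.475 (ligation) and 0.439 to 0.518 (CCl4), the median differences from 0.775 to 1.11 and 0.789 to 1.17. Lists called ran from 1 to 4 (culture), 5 to 10 (coculture minus culture) and 4 to 7 (between injuries). A coculture group of 1 array was assumed to vary like the other groups. Scalings moved the share of higher calls by under 10 percentage points but turned the majority after ligation (47.6% to 56.0%), after CCl4 (43.3% to 52.8%) and in coculture minus culture (54.4% to 49.2%). A linear-scale alternative was not run because the values are log2. Genes near background limit what can be seen, with 6803 to 7037 of 18193 at log2 5 or more per array.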

Other observations

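The values here were picked after the results were seen, and no test was added for them. Transcripts typical of other cells differed between markers of the same cell type. S100a8, Lcn2 and Mmp8 stood at 9.88, 12.0 and 4.97 in coculture against 1.77, 2.99 and 1.72 in culture, while S100a9, the partner of S100a8 in neutrophils, stood at 1.30, and Krt19, a cholangiocyte keratin, stood at 5.60 in coculture against 2.33 in culture and 1.58 in quiescent cells, with Epcam below the filter. Lyz1 was at 7.37 in culture, 7.99 in coculture, 8.30 after ligation and 7.90 after CCl4 against 2.49 in quiescent cells, while Csf1r, the macrophage growth factor receptor, stayed at 3.28 to 4.05 in all groups. After ligation Tyrobp, Cd5l, Vsig4 and Fcgr3 stood at 3.21, 3.27, 2.79 and 3.28 against 1.46, 1.20, 1.31 and 1.72 in quiescent cells, all of them macrophage markers below the filter, and the median of the 24 macrophage markers was 2.89 against 1.77. Cd68, a lysosomal gene, stood at 7.02 in quiescent cells, 3.74 in culture and 7.82 in coculture. Eng, which endothelial and stellate cells share, lay between 8.36 and 9.66, while the endothelial genes Stab2, Lyve1 and Pecam1 stayed at background.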
